A study of Mus musculus with 8 samples.

How the data were processed

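Gene expression was measured on 8 Illumina bead arrays, 1 per sample, in mouse bone marrow-derived macrophages. The cells received a scramble control siRNA (siCTL) or an siRNA against Bcl3 (siBcl3) and were then exposed to lipopolysaccharide (LPS) for 0 or 8 h, which gives 4 groups of 2 samples. Per the labels' protocols, RNA was extracted with an RNeasy kit and checked on a Bioanalyser, and biotinylated cRNA was made with the Ambion MessageAmp kit. Groups were taken from the labels. Chip, position on the chip and hybridization day are not given in the sources used here, so no batch could be tested.

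The authors deposited a table of bead signal intensity per probe and array, and a table of processed intensity values for the same arrays. BeadStudio 2010.3.0.30128 is named per the submitters' processing notes. How the authors corrected background and normalized is not given in the sources used here. In the first table no intensity lay below 0 and the quartiles differed between arrays, so its values were taken as neither background-corrected nor normalized. The processed values were on a linear scale with array medians of 45.2 to 45.4, so they had been normalized between arrays by a method that stays unknown. Each processed column had a Spearman correlation of 0.9983 to 0.9999 across probes with its own array in the first table and of at most 0.9025 with any other array.

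Both tables held 25697 probes. The platform annotation gave 1 gene symbol for 23978 of them, several symbols for 0 and none for 1719. Of the named probes, 23962 were matched by Entrez number to a current gene table and 16 were not.

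Neither table held detection p-values or control probes, which the planned filter on dim probes needed. A substitute was chosen after the data were seen. The 1338 probes for olfactory, vomeronasal and taste receptors, which macrophages are presumed not to express, stood for background. The detection p of a probe on an array was the share of these chemosensory probes with at least its signal. Probes with a detection p under 0.05 on at least 2 of the 8 arrays were kept, which left 11373 probes, 123 of the chemosensory ones (9.2%) among them. For each gene the kept probe with the highest mean over all 8 arrays was used, and unnamed probes were kept as they were, which gave 8172 named genes and 661 unnamed probes, 8833 in all and called genes below. A group in which a gene was above background on no array gives only a bound on its fold change, computed from the lowest normalized signal among probes above background and written as "at least".

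Signals were background-corrected by normexp with an offset of 50, quantile normalized and put on the log2 scale in limma 3.58.1 (R 4.3.3). The offset draws the fold changes of dim genes toward 0. One model with 4 group means was fitted over all 8 arrays, so that all groups shared 1 estimate of the spread (4 residual and 6.25 prior degrees of freedom). The contrasts were the LPS response in siCTL and in siBcl3, the Bcl3 siRNA effect at 0 h and at 8 h, their interaction, and the average LPS and siRNA effects. A gene was called at an adjusted p under 0.05 (limma's moderated test, two-sided, Benjamini-Hochberg over the 8833 genes). Standard errors (SE) are limma's. Precision is limited by the number of arrays: the median SE was 0.081 log2 units for a difference between a pair of groups, 0.114 for the interaction and 0.057 for the averages.

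The named genes are Bcl3 and, for the LPS response in siCTL and the siRNA effect at 8 h, at 0 h and averaged, the 10 largest changes per direction among called genes whose arrays did not overlap between groups. Probes without a gene symbol and symbols that are clone or locus names are counted but not named, even where their change is larger. With 2 arrays against 2, chance alone gives no overlap in 33.3% of genes. For the interaction up to 5 called genes per direction are named, and for each gene list up to 4 members with the largest change. Further called members of a list, where it moved both ways or few of its genes were called, and the genes of other sets were named after their values were seen.

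Gene lists were written from general knowledge: 27 lists of pathways and cell-type markers, of which 21 had at least 3 measured genes and were tested. Each list was tested with camera (limma) with a preset correlation of 0.01, Benjamini-Hochberg over lists. Camera with an estimated correlation and fry were the alternatives. LPS-responsive genes were those called for the average LPS effect with a log2 change of at least 1 (227 induced) or at most -1 (84 repressed). In the fit of all 8 arrays the errors of the average LPS effect are uncorrelated with those of the siRNA effect at either time, and exchanging the siRNA labels gives the same 227 and 84 genes. With 1 array left out and sets chosen anew the errors can be correlated, so these fits were also run with the sets of all 8 arrays (added after the data were seen). The groups, contrasts, naming rule, lists and most alternatives were fixed before the data were examined.

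The fit was tested on simulated data, with 200 of the 8833 genes changed in each of 10 simulations per comparison. At a log2 change of 0.5 it called 83.4% of changed genes for the LPS response in siCTL, 85.1% for the siRNA effect at 8 h and 83.6% for that at 0 h. At a log2 change of 1 it called 98.4%, 98.8% and 98.8%. Of all calls 6.4%, 8.1% and 7.2% were false, above the nominal level of 5%. In 10 simulations of the effect at 8 h, a list of 32 genes shifted by -0.3 was called 10 times, and unshifted lists were called in 3 of 200 tests. The noise was drawn separately for each gene, so these simulations do not test the list calls for correlated genes. It was normal noise with limma's moderated spread. The 200 changed genes were also far fewer than the 2492 called for LPS in siCTL. These shares therefore need not hold for the real calls.

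The alternatives tried were no background correction, median scaling, cyclic loess, the authors' processed values, neqc with the chemosensory probes as negative controls (offset 16, added after the data were seen), no filter and a stricter filter on dim probes (detection p under 0.01 on at least 4 arrays, 8223 probes), the mean of all probes of a gene, eBayes with trend and robust options, a replicate block, only the arrays of the groups compared, an added 2-fold threshold, and leaving out each array in turn. Normexp with an offset of 50, foreseen for files without negative controls, was therefore the setting used throughout and is not a separate result. Lists with fewer than 3 measured genes were left out. Plots were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.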

Results

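The series profiled gene expression in mouse macrophages in which Bcl3 was knocked down. Bcl3 is an atypical member of the IκB family that binds NF-kB subunits in the nucleus. Bone marrow-derived macrophages of C57BL/6 mice aged 5 to 7 weeks were grown in medium with 25% serum and 25% L cell-conditioned medium, the source of the growth factor M-CSF. They were transfected with scramble siRNA (siCTL) or Bcl3 siRNA (siBcl3) and given LPS, a bacterial cell-wall component sensed by Toll-like receptor 4, for 0 or 8 h. There were 2 arrays in each of the 4 groups. Median signal per array was 44.8 to 46.4 units, and 8837 to 10338 of 25697 probes lay above background. Replicates of a group correlated at r = 0.9923 to 0.9948 across genes, which are not independent replicates. The first principal component held 78% of the variance and the second 10.9%. The labels do not say whether replicates were separate cultures or animals, so p-values measure only the spread between these samples. The number of arrays limits the precision of every value.

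The targeted gene was examined first. The Bcl3 probe (ILMN_2749717) gave 72.5 and 75.8 units in siCTL at 0 h and 140.6 and 114.1 units at 8 h. In siBcl3 it gave 59.4 and 52.6 units at 0 h and 66.9 and 62.7 units at 8 h. These signals were low: in siBcl3 at 0 h they stood 18 and 11 units above the median chemosensory probe. On the normalized log2 scale Bcl3 was 6.47 ± 0.06 (SD, n = 2) in siCTL at 0 h, 7.29 ± 0.11 in siCTL at 8 h, 6.17 ± 0.09 in siBcl3 at 0 h and 6.47 ± 0.05 in siBcl3 at 8 h. LPS raised Bcl3 in siCTL by 0.82 ± 0.08 log2 units (SE, limma adjusted p = 3.48e-05). At 8 h the siRNA lowered Bcl3 by a log2 change of -0.82 ± 0.08 (adjusted p = 0.00131), to 56.6% of the control, and with neqc background correction to 39.6%. At 0 h the change was -0.30 ± 0.08 and was not called (adjusted p = 0.0548, 0.015 to 0.29 over the alternatives). It was called without background correction (76.6% of the control, adjusted p = 0.0361) and with neqc (62.9%, 0.0178). Cyclic loess (76%, 0.0273) and the authors' values (70.8%, 0.015) called it too. In the main fit Bcl3 at 0 h stood at 81.2% of the control, and with 1 array left out the change was -0.364 to -0.237. Averaged over both times Bcl3 fell by 0.56 ± 0.06 (adjusted p = 0.00038).

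**Figure D1:**
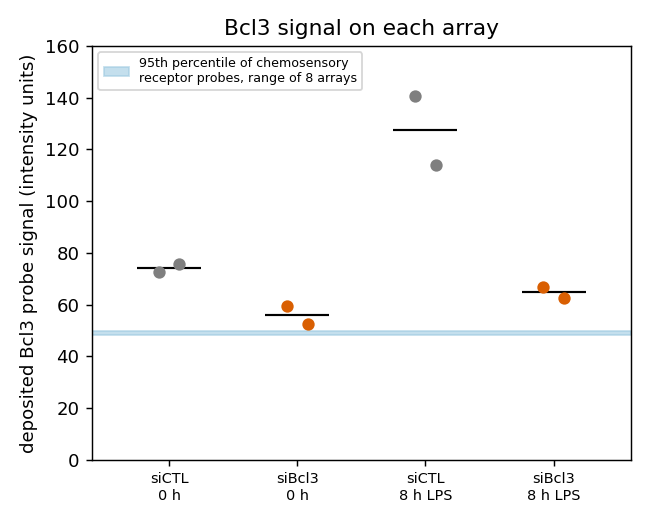
Bcl3 signal on each of the 8 arrays (y axis, bead signal units) by group (x axis), with points for arrays, lines for group means and a band for the 95th percentile of chemosensory receptor probes (48.3 to 49.6 units). The siCTL arrays at 8 h gave 140.6 and 114.1 units and the siBcl3 arrays at 8 h 66.9 and 62.7 units.

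The first comparison asked how control macrophages responded to 8 h of LPS. The cytokine genes Il1b and Il1a, which encode both forms of interleukin 1, rose by 5.93 ± 0.12 and 4.36 ± 0.11 log2 units (limma adjusted p = 1.14e-09 and 1.69e-09). Tnf rose by 3.83 ± 0.14 and Il6 by 3.44 ± 0.19, and Il10, an anti-inflammatory cytokine, was at least 12.7-fold higher. Among chemokines Cxcl2, a neutrophil attractant, rose by 5.57 ± 0.13, the interferon-inducible Cxcl10 by 4.39 ± 0.13 and Ccl3 by 3.77 ± 0.19. Edn1, which encodes endothelin 1, rose by 3.80 ± 0.17 and the activation antigen Cd69 by 3.51 ± 0.11. Log2 changes were -2.46 ± 0.09 for the cholesterol ester hydrolase gene Nceh1, -2.34 ± 0.07 for the ceramide kinase gene Cerk and -2.34 ± 0.10 for the iron exporter gene Slc40a1. Fblim1 (-2.04), Tmem86a (-2.03), Nrros (-1.99), Snx24 (-1.91), Rab7b (-1.86), Lhfpl2 (-1.77) and Arl11 (-1.61) also fell (adjusted p at most 1.33e-05).

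Whole gene groups moved with LPS in control cells. Of 18 measured inflammatory cytokines 17 rose over all genes tested and 18 adjusted over the list alone, with a median log2 change of 1.05 (camera adjusted p = 2.05e-18). Il1b, Il1a, Tnf and Il6 led this list. In the NF-kB list 17 of 18 genes rose, likewise adjusted over the list alone, led by Traf1 (2.93), Nfkbia (2.60), Tnfaip3 (2.42) and Nfkbiz (2.11). Of 32 interferon response genes 26 rose and 1 (Irgm1, -0.45) fell, the same counts adjusted over the list alone, with a median of 0.85. Ifnb1, the interferon beta gene, was at least 8.36-fold higher, and Oasl1 (3.02), Cmpk2 (2.88) and Isg15 (2.70) followed. Among 16 chemokines 10 rose and Ccl6 fell (-0.82), the same counts adjusted over the list alone. Antimicrobial and inflammatory effectors rose in 16 of 22 cases and fell in 1, Plau (17 and 1 adjusted over the list alone), with Edn1, Gch1 (2.20), Nos2 (1.90) and Lcn2 (1.89) in front. Anti-inflammatory mediators rose in 14 of 19 cases and fell in 1, Tsc22d3 (15 and 1 adjusted over the list alone), led by Il10, Zfp36 (2.99), Socs3 (2.11) and Il1rn (1.92). These lists and the Toll-like receptor list (10 of 18 higher and Tlr4 lower, also adjusted over the list alone) were called with the preset (adjusted p = 2.05e-18 to 1.65e-05) and with an estimated correlation (adjusted p = 0.00821 to 0.031).

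Across the genome 2492 of 8833 genes were called for LPS in control cells, 958 higher and 1534 lower. Of these, 276 changed at least 2-fold, 213 higher and 63 lower. Under median scaling 578 were higher and 1838 lower, and with cyclic loess 1103 and 1190. Of 708 called genes with several probes, 10 had a probe called the other way. All 20 named genes were called again in each of the 8 fits with 1 array left out and under all 5 other ways to correct and normalize.

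The main comparison asked what Bcl3 siRNA changed in macrophage cultures after 8 h of LPS. A changed cell mix was not separated from a change per cell. The dendritic cell marker list, with 1 measured gene, was not tested. Unnamed probes aside, the largest decreases were in F10, the coagulation factor X gene, with a log2 change of -1.33 ± 0.10 (SE, limma adjusted p = 0.000469), and in genes of antigen presentation on MHC class II. H2-Ab1 and H2-Eb1, which encode class II chains, changed by -1.28 ± 0.25 and -1.21 ± 0.26, and Cd74, the invariant chain, by -1.23 ± 0.20 (adjusted p = 0.025, 0.038 and 0.0128). The integrin gene Itgb7 (-1.13 ± 0.15), the cytohesin-binding Cytip (-1.08 ± 0.20) and Serping1, the complement C1 inhibitor gene (1.99-fold lower, adjusted p = 0.0128), also fell. Flrt3 (-0.96), Krt16 (-0.92) and Edn1 (-0.82) completed the 10 named genes that fell, and with 1 array left out H2-Ab1 came down to -0.849, Flrt3 to -0.576 and Edn1 to -0.476. The chemokine gene Ccl6 rose by 1.18 ± 0.18 (adjusted p = 0.00825), Cd69 by 1.10 ± 0.11 (0.00131) and Alox5ap, needed for leukotriene synthesis, by 1.06 ± 0.11 (0.00141). Acta1, an actin gene not above background in siCTL, was at least 1.77-fold higher. Cd52 (0.90 ± 0.10), Ppfia3 (0.89 ± 0.11), Rnase4 (0.87 ± 0.13), the acid ceramidase gene Asah1 (0.85 ± 0.09), the nucleotide receptor gene P2ry6 (0.85 ± 0.08) and Ebi3, a cytokine subunit gene (0.84 ± 0.13), rose as well.

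Several gene groups shifted at 8 h. In the antigen presentation list 4 of 18 genes fell, H2-DMb1 (-0.70) besides the 3 named, against 1 higher and 6 lower adjusted over the list alone. The class II genes H2-Aa (-0.58, limma adjusted p = 0.205) and H2-DMa (-0.42, 0.388) and their regulator Ciita (-0.18, 0.495) were not called. The list's median was -0.14 (camera adjusted p = 0.0106, but 0.666 with an estimated correlation). In the glycolysis and hypoxia list 3 of 14 genes fell (1 higher and 4 lower adjusted over the list alone): Ldha (-0.54 ± 0.09), Pfkl (-0.50) and Egln3, which was at least 1.18-fold lower. The list's median was -0.15 (adjusted p = 0.008, and 0.243 with an estimated correlation). Macrophage markers had a median of 0.31 (adjusted p = 0.00212, and 0.243 with an estimated correlation), with Trem2 (0.54), C1qa (0.50) and C1qb (0.40) higher. Adjusted over the list alone, 8 of these 14 markers were higher and 2 lower. Of 18 inflammatory cytokine genes Ebi3, Il27 (0.52), Il1a (0.51), Osm (0.50) and Il23a (0.37) rose and Csf3 (-0.36) fell (8 higher and 3 lower adjusted over the list alone), and the list itself was not called (median 0.14, adjusted p = 0.0613). Of 32 interferon response genes 1, Ifnb1 (0.69, adjusted p = 0.00182), rose, and 1 rose and 1 fell adjusted over the list alone. Their median was -0.05 and their mean 0.01, and the list was not called (adjusted p = 0.91).

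In all, 282 genes were called at 8 h, 153 higher and 129 lower, and 10 of them changed at least 2-fold. With only the arrays compared 429 genes were called. Single arrays weighed heavily: the count was 49 without siCTL 8 h replicate 1, 32 without siCTL 8 h replicate 2 and 22 without siBcl3 8 h replicate 1. Under median scaling 48 genes were called, and Ccl6, Rnase4, H2-Ab1, H2-Eb1, Cytip, Serping1, Flrt3, Krt16 and Edn1 were lost, Edn1 also with neqc. Of the 20 genes named, 8 were called in every fit with 1 array left out: Cd69, Alox5ap, Acta1, Cd52, Ppfia3, Asah1, P2ry6 and F10. Krt16 was lost without siBcl3 8 h replicate 1, and the other genes, H2-Ab1, Cd74 and H2-Eb1 among them, also without either siCTL 8 h array. The antigen presentation list was not called without siCTL 8 h replicate 1 or siBcl3 8 h replicate 1, and the glycolysis and macrophage lists not without siBcl3 8 h replicate 1 (list medians over the 8 fits -0.20 to -0.11, -0.18 to -0.09 and 0.22 to 0.35). With fry, another list test, none of these 3 lists was called (adjusted p = 0.353, 0.0506 and 0.0506).

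**Figure D2:**
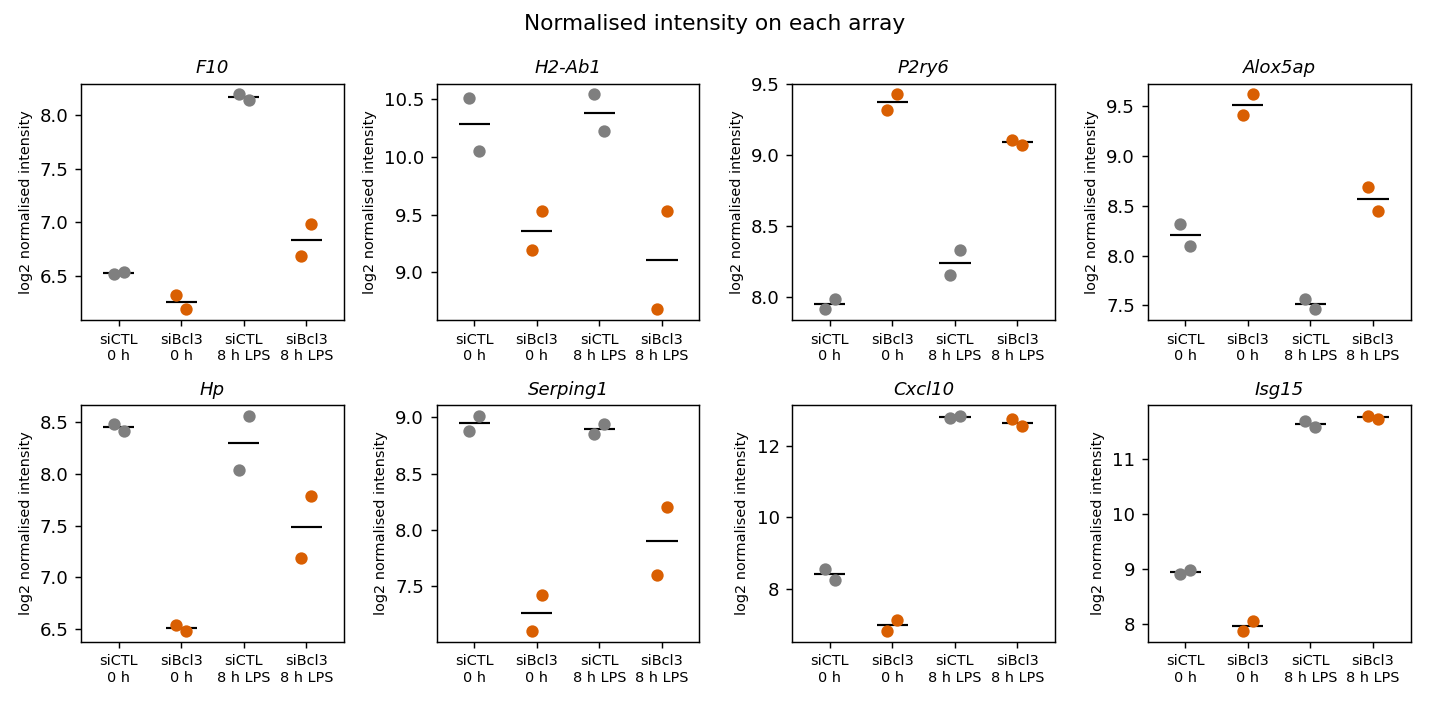
Normalized log2 signal (y axis) of F10, H2-Ab1, P2ry6, Alox5ap, Hp, Serping1, Cxcl10 and Isg15 on each of the 8 arrays, by group (x axis), with points for arrays and lines for group means. Mean F10 was 8.17 in siCTL and 6.84 in siBcl3 at 8 h, and mean P2ry6 7.95 in siCTL and 9.38 in siBcl3 at 0 h.

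The same comparison without LPS asked what Bcl3 siRNA changed in macrophage cultures at rest. Stromal markers fell in the same comparison (below). For any gene that stromal cells also express, a changed cell mix was not separated from a change per cell. This holds here, in the averaged effect and in the interaction. Ptx3, a soluble pattern recognition molecule, and Hp, haptoglobin, both changed by -1.94 log2 units (SE 0.21 and 0.19, limma adjusted p = 0.000753 and 0.000512), and Serping1 by -1.69 ± 0.17 (0.000549). The chemokine genes Cxcl9 and Cxcl10, which interferon induces, changed by -1.43 ± 0.29 (adjusted p = 0.0155) and -1.42 ± 0.13 (0.000331). Gja1, the gap junction protein connexin 43, changed by -1.39 ± 0.15, the cyclin gene Ccnd2 by -1.36 ± 0.30 and Itgb7 by -1.31 ± 0.15. The prolactin-family genes Prl2c3 (-2.08 ± 0.21) and Prl2c4 (-1.70 ± 0.21) are near-identical paralogs, so their probes may share signal and their separate values are uncertain. P2ry6 rose by 1.43 ± 0.08 (adjusted p = 5.65e-05), Alox5ap by 1.31 ± 0.11 (0.000203) and Ccl6 by 1.06 ± 0.18 (0.00551). Hmox1, the heme oxygenase 1 gene, rose by 1.05 ± 0.11, Cmtm3 by 1.01 ± 0.08, Ebi3 by 0.95 ± 0.13 and the cyclin gene Ccnd1 by 0.92 ± 0.11. Ccl3 (0.91), Rnase4 (0.91) and the growth factor gene Igf1 (0.85) rose too.

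Interferon response genes and stromal markers were both lower at 0 h. Of 32 interferon response genes 11 fell (13 adjusted over the list alone), with a median log2 change of -0.24 (camera adjusted p = 1.43e-10, and 0.11 with an estimated correlation). Gbp3 (-1.15), Isg15 (-0.99), Usp18 (-0.86) and Igtp (-0.85) changed most. The list of fibroblast and stroma markers had a median of -0.41 (adjusted p = 4.29e-06, and 0.11 with an estimated correlation), with 4 of 7 genes lower (6 adjusted over the list alone). They were Dcn, a matrix proteoglycan gene (-1.31), Sparc (-0.99), Cxcl12 (-0.46) and the collagen gene Col1a1 (-0.34). Antigen presentation genes had a median of -0.29 (adjusted p = 1.75e-05, and 0.276 with an estimated correlation), and Cd86 (-0.69), Ciita (-0.54) and Tap1 (-0.41) fell (3 lower, and 7 adjusted over the list alone). H2-Ab1 changed by -0.92 and was not called (adjusted p = 0.0513). The list's median was -0.45 to -0.19 over the 8 fits with 1 array left out. Antimicrobial and inflammatory effectors had a median of -0.13 (adjusted p = 0.00625, and 0.11 with an estimated correlation). Among them Hp, Mmp13 (-1.13), Slpi (-1.07) and Nos2 (-0.84) fell, and in all 6 fell and 2, Gch1 and Mmp9, rose (9 and 3 adjusted over the list alone).

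Further lists moved at 0 h. Glycolysis and hypoxia genes had a median of -0.19 (adjusted p = 0.000792, and 0.11 with an estimated correlation), with Ldha (-0.53), Pfkl (-0.46) and Pgam1 (-0.37) lower (3 of 14, and 4 adjusted over the list alone). Stress response genes of the unfolded protein and integrated stress pathways had a median of -0.16 (adjusted p = 0.00625, and 0.11 with an estimated correlation), with Ddit3 (-0.73), Ddit4 (-0.54) and Asns (-0.47) lower (3 of 13, also adjusted over the list alone). Macrophage markers had a median of 0.18 (adjusted p = 0.00625, and 0.11 with an estimated correlation), and the complement genes C1qb (0.59), C1qa (0.58) and C1qc (0.55) rose (3 of 14, and 6 adjusted over the list alone). The list's median was 0.11 to 0.38 over the 8 fits with 1 array left out. Chemokines went both ways, with Ccl3, Ccl4 (0.81), Ccl6 and Ccl12 (0.49) higher and 6 of 16 lower, Cxcl1 (-1.15) and Ccl2 (-0.61) among these (6 higher and 7 lower adjusted over the list alone). Their median was 0.05, their mean -0.11, and the test, directed downward, did not call them (adjusted p = 0.697).

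At 0 h 642 genes were called, 316 higher and 326 lower, and 36 changed at least 2-fold, 5 higher and 31 lower. Under median scaling 498 were higher and 103 lower, and with only the arrays compared 304 genes were called. The count was 214 without siBcl3 0 h replicate 1 and 369 without siBcl3 0 h replicate 2. Of the 20 named genes 17 were called in every fit with 1 array left out. Ccl3 and Cxcl9 were lost without siCTL 0 h replicate 1 or siBcl3 0 h replicate 1 (adjusted p up to 0.13 and 0.119 over the alternatives). Ccnd2 was lost without siCTL 0 h replicate 2, siBcl3 0 h replicate 1 or either siCTL 8 h array (up to 0.168). Under median scaling Cxcl9, Ccnd2 and the stress response list were not called, and with fry the antigen presentation list was not (adjusted p = 0.107). In the main fit more genes were called at 0 h than at 8 h (642 and 282). With only the arrays compared the order was reversed (304 and 429). Bcl3 itself was called at 8 h only in the main fit (56.6% of the control, and 81.2% at 0 h), whose offset draws dim genes toward 0. With neqc it was called at both times (39.6% of the control at 8 h and 62.9% at 0 h). Whether the changes at 0 h or at 8 h stem from lower Bcl3 was not tested.

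**Figure D3:**
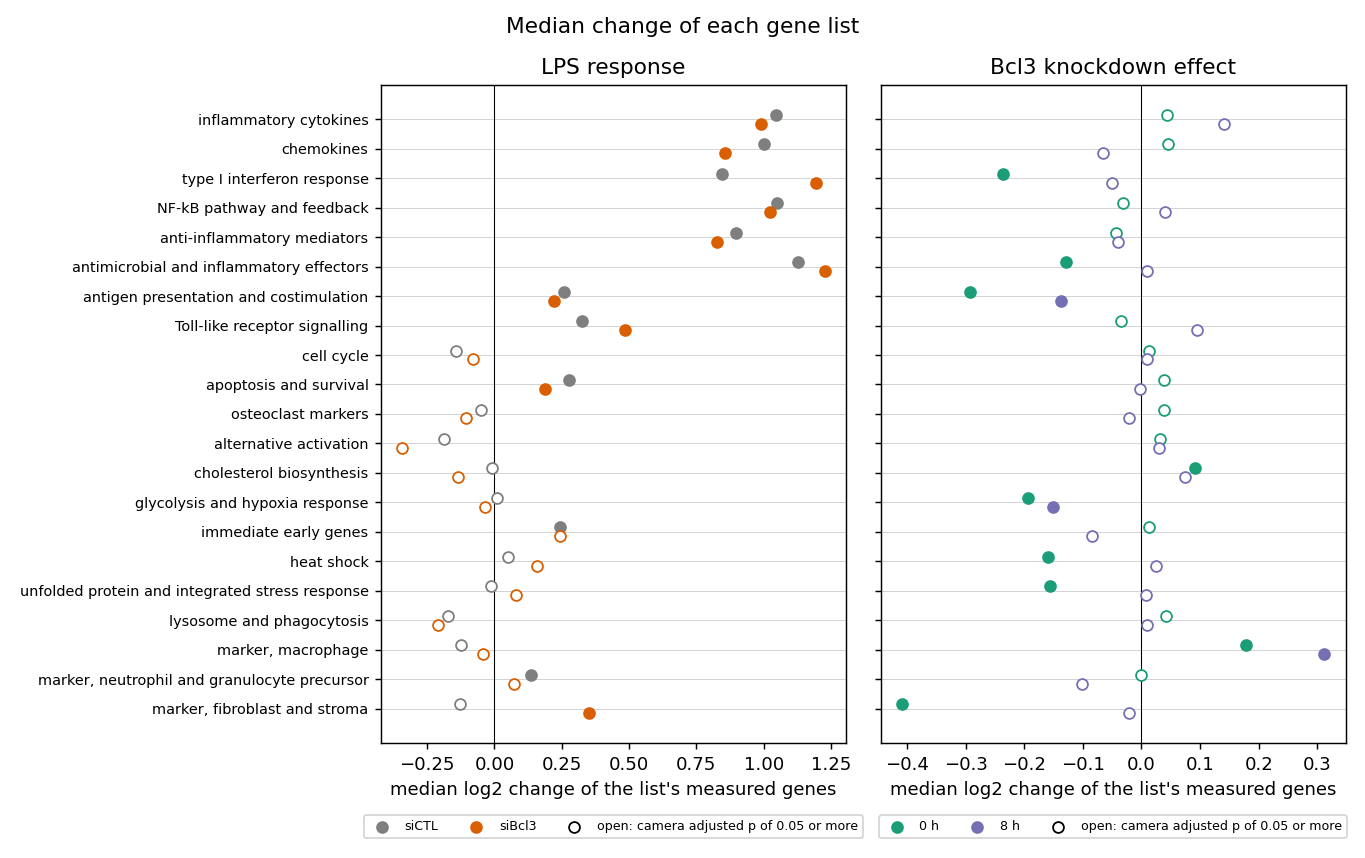
Median log2 change (x axis) of each tested gene list (y axis) for the LPS response in siCTL and siBcl3 (left) and the siRNA effect at 0 h and 8 h (right), with filled points for lists that camera called with the preset correlation. The interferon response list lies at 0.85 for LPS in siCTL, and at -0.24 for siRNA at 0 h and -0.05 at 8 h.

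The siRNA effects at both times were set side by side and averaged. These effects share no arrays, and an average can be carried by 1 time. Alox5ap rose on average by 1.18 ± 0.08 log2 units (SE, 4 arrays against 4, limma adjusted p = 4.8e-05), P2ry6 by 1.14 ± 0.06 (1.72e-05) and Ccl6 by 1.12 ± 0.12 (0.000537). Ebi3 (0.90), Rnase4 (0.89), Igf1 (0.84), Cmtm3 (0.80) and Cd52 (0.77) rose on average as well, as did the platelet factor gene Pf4 (1.09 ± 0.22, adjusted p = 0.0111) and the chemokine gene Ccl9 (0.81 ± 0.18, 0.0161). Hp changed by -1.37 ± 0.13, Serping1 by -1.34 ± 0.12, Cxcl9 by -1.29 ± 0.21 and Itgb7 by -1.22 ± 0.11. Ptx3 (-1.11), H2-Ab1 (-1.10), Cytip (-1.05), the ubiquitin-like Ubd (-1.05) and the paralogs Prl2c3 (-1.48) and Prl2c4 (-1.29) also fell. At 8 h alone Ptx3 changed by -0.28 and was not called (adjusted p = 0.556). Prl2c3, Prl2c4 and Cxcl9 were called at 0 h only, H2-Ab1 at 8 h only, and Ubd, Pf4 and Ccl9 at neither time. In total 955 genes were called, 473 higher and 482 lower. The count was 537 without siBcl3 0 h replicate 1, 569 without siBcl3 8 h replicate 1, 573 and 611 without siCTL 8 h replicates 2 and 1, and 484 under median scaling, where Ccl9 and Ubd were lost. Pf4 and Ubd were lost without siCTL 8 h replicate 1 or siBcl3 8 h replicate 1 (adjusted p up to 0.0897 and 0.0971), and Ccl9 without these, siCTL 8 h replicate 2 or siBcl3 0 h replicate 1 (up to 0.0752).

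Across the 8833 genes, which are not independent replicates, the effects at 0 h and 8 h correlated at r = 0.511 (Spearman 0.366). Of 133 genes called at both times, 72 were higher at both (5.5 for independent lists) and 60 lower at both (4.8 for independent lists). The remaining gene was Ptgs2, the cyclooxygenase 2 gene, at -0.56 at 0 h and 0.51 at 8 h. Calls at both times rest on 1 spread estimate per gene, so a gene with a small spread is more readily called at both. The counts for independent lists are therefore a low reference. Of the 642 calls at 0 h 543 had the same sign at 8 h, and of the 282 calls at 8 h 257 had the same sign at 0 h.

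**Figure D4:**
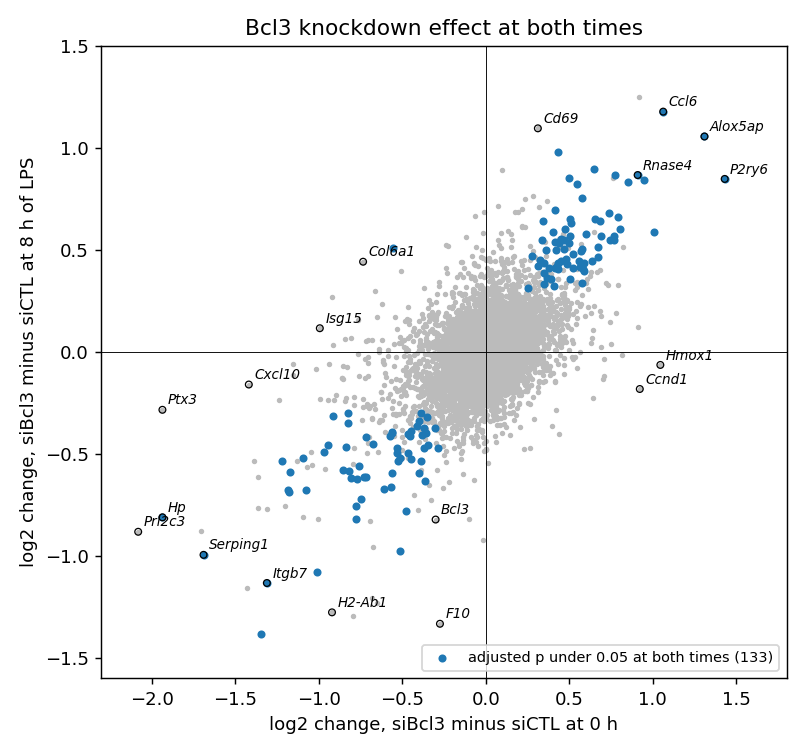
Log2 change with Bcl3 siRNA at 0 h (x axis) against that at 8 h (y axis), with 1 point per gene and blue points for genes called at both times. The effects correlated at r = 0.511 across 8833 genes, and of 133 genes called at both times all but Ptgs2 had the same sign.

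The next comparison asked whether the siRNA altered the response to LPS. In siBcl3 LPS raised 1183 genes and lowered 1915. The responses in siBcl3 and siCTL share no arrays and correlated at r = 0.919 across genes, with 794 genes higher in both and 1238 lower in both (128.3 and 332.6 for independent lists). A further 12 genes were called in opposite directions, P2ry6 (0.29 in siCTL and -0.29 in siBcl3), Fscn1 (-0.48 and 0.44) and Hvcn1 (0.54 and -0.28) among them. Here too the calls share 1 spread estimate per gene, so the counts for independent lists are a low reference. Bcl3 itself rose in siBcl3 by 0.30 ± 0.08 log2 units (limma adjusted p = 0.0159), a call lost under median scaling and without siBcl3 0 h replicate 2 or siBcl3 8 h replicate 1. Its interaction was -0.52 ± 0.12 (adjusted p = 0.106, not called). The interaction was called for 30 genes, 18 with a higher and 12 with a lower siRNA effect at 8 h than at 0 h. Cxcl10 went from -1.42 at 0 h to -0.16 at 8 h (interaction 1.26 ± 0.18, adjusted p = 0.0245), and the ubiquitin-like interferon gene Isg15 from -0.99 to 0.12 (1.11 ± 0.12, 0.0128). Ptgs2 (interaction 1.06), the collagen gene Col6a1 (1.18) and Phf11d (0.96) behaved in the same direction. Hmox1 went from 1.05 to -0.06 (-1.11 ± 0.15, adjusted p = 0.0205), Ccnd1 from 0.92 to -0.18 (-1.10 ± 0.15, 0.0222) and F10 from -0.27 to -1.33 (-1.06 ± 0.14, 0.0153). Ubl3 (-0.86) and the phosphatase gene Dusp6 (-0.84) also had lower effects at 8 h. None of these 10 genes was called in all 8 fits with 1 array left out. In those fits limma called 66 and 25 genes without siCTL 0 h replicates 1 and 2, 0 and 22 without siBcl3 0 h replicates 1 and 2, 0 and 1 without siCTL 8 h replicates 1 and 2, and 0 and 1 without siBcl3 8 h replicates 1 and 2. Where it called 0 genes, 681, 770 and 857 had an unadjusted p under 0.05. Under median scaling 2 genes were called, Ccnd1 alone among these 10, and with neqc Phf11d, F10, Ubl3 and Dusp6 were lost.

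Interferon response genes as a group had a siRNA effect 0.35 log2 units higher at 8 h than at 0 h (list median, camera adjusted p = 7.94e-12, and 0.166 with an estimated correlation). Of its 32 genes 2 were called and 11 adjusted over the list alone. The 2 were Isg15 and Ifnb1, but Ifnb1 was above background on no array at 0 h, so its siRNA effect there was not measured. The fibroblast and stroma list (0.44, adjusted p = 8.65e-06) and the stress response list (0.23, 0.00484) moved likewise, with 0 genes called in limma, 5 and 2 adjusted over the list alone, and 5 and 3 at an unadjusted p under 0.05. With an estimated correlation neither was called (adjusted p = 0.166 for both), and with fry none of the 3 lists was (adjusted p = 0.08 for each). The stress response list was also lost under median scaling and without siCTL 0 h replicate 2 (medians 0.14 to 0.26 over the 8 fits).

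The last comparison asked whether genes that answer to LPS were shifted by the siRNA at 8 h. The 227 LPS-induced genes had a median siRNA effect of 0.03 log2 units, with 18 called higher and 13 lower (camera p = 0.563, and 0.446 with an estimated correlation). The 84 LPS-repressed genes had a median of -0.02, with 2 higher and 3 lower (camera p = 0.744, and 0.79 with an estimated correlation). The induced counts were 9 and 2 without siCTL 8 h replicate 1, 6 and 2 without siCTL 8 h replicate 2, 5 and 2 without siBcl3 8 h replicate 1, and 5 and 2 under median scaling. The repressed counts were 9 and 1 with neqc, 6 and 2 without background correction, and in limma 0 and 0 without either siCTL 8 h array or siBcl3 8 h replicate 1. For neither set did the test detect a shift against other genes, and each median had the opposite sign under at least 1 other normalization.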

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

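The tests of a smaller stromal share, of normalization, of weaker LPS-like activation and of a response to the control siRNA were chosen only after the results they address were seen. A test of the difference itself singled out 30 genes whose response to Bcl3 siRNA was not the same at 0 h and 8 h of LPS. Cxcl10, a chemokine gene, had a log2 effect 1.26 higher at 8 h than at 0 h, the collagen gene Col6a1 1.18, the interferon gene Isg15 1.11, the cyclooxygenase gene Ptgs2 1.06 and Phf11d 0.96. The effect on the heme oxygenase gene Hmox1 was lower at 8 h (-1.11), as were those on the cyclin gene Ccnd1 (-1.10), the coagulation factor gene F10 (-1.06), Ubl3 (-0.86) and the phosphatase gene Dusp6 (-0.84). By list median, the effect at 8 h lay above that at 0 h by 0.353 for interferon response genes, 0.233 for stress response genes and 0.438 for stromal markers. None of the 3 lists was called with an estimated correlation (adjusted p = 0.166 for each) or with fry (0.08 for each). Without siCTL 0 h replicate 2 or under median scaling the stress response list was not called, and the interferon and stromal lists were called in all 8 fits with 1 array left out. Called genes numbered 66 without siCTL 0 h replicate 1, 25 without siCTL 0 h replicate 2 and 22 without siBcl3 0 h replicate 2. They numbered 1 without siCTL 8 h replicate 2 and 1 without siBcl3 8 h replicate 2. In limma they numbered 0 without siCTL 8 h replicate 1, siBcl3 0 h replicate 1 or siBcl3 8 h replicate 1, where 770, 681 and 857 genes had an unadjusted p under 0.05.

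Stromal markers were lower with Bcl3 siRNA at 0 h (list median -0.41, not called with camera's estimated correlation, adjusted p = 0.11). Under the 5 other ways to correct and normalize the median was -0.827 to -0.414. Dcn and Sparc, at 664.6 and 488.8 units above background in siCTL, were the brightest of the measured genes. Normalization is argued against as the cause, because the list's change against all genes, taken per array, was at its closest to 0 over 5 other ways to correct and normalize -0.421 ± 0.059 (SE between arrays). A smaller share of stromal cells in the siBcl3 cultures, which the labels neither mention nor rule out by a sort, is a candidate explanation and cannot be told apart from lower expression per cell: it needs all markers to fall by 1 ratio, and only Dcn and Sparc were bright enough to test this (Cochran's Q across genes with neqc values, by its chi-squared approximation, p = 0.257, too few genes to decide). The same chi-squared approximation over 6 genes, dim ones included but without Lum, which missed the stricter detection threshold, was run before that one and gave p = 0.0031, against 1 common ratio (at 8 h p = 6.5e-07 around a pooled change of 0.08), but the dim genes were at most 52.8 units above background, where changes are compressed (-0.89 to -0.45). No other list holds any of the 8 genes written for this one, and which of them macrophages express was not measured, so a direct effect of the siRNA stays open and untested.

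Interferon response genes were lower with Bcl3 siRNA at 0 h (list median -0.24, not called with camera's estimated correlation, adjusted p = 0.11), while their median at 8 h was -0.05. Under the 5 other ways to correct and normalize the median at 0 h was -0.434 to -0.184. The difference between the times was not called with an estimated correlation (adjusted p = 0.166) or fry (0.08). A uniformly weaker LPS-like activation of the siBcl3 cultures is argued against as the whole cause, since 17 LPS-induced genes were called higher at 0 h beside 49 lower, where the false discovery rate allows 3.3, although without siBcl3 0 h replicate 1 these counts were 5 and 24. LPS-repressed genes went with it, however (median 0.16, 28 called higher and 1 lower), so a weaker activation of part of the LPS-responsive genes stays open. Normalization is argued against as the whole cause: the list's change against all genes, taken per array, was at its closest to 0 over 5 other ways -0.256 ± 0.082 (SE between arrays), under median scaling, below a 95% bound of -0.227. An interferon response to the control siRNA cannot be told apart from a loss of interferon signalling with Bcl3 siRNA, because only 1 control siRNA condition was run at 0 h. Off-target action of the Bcl3 siRNA stays open because only 1 Bcl3 siRNA condition was run at 0 h. The same holds at 8 h, and so for every siRNA effect given here.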

How the results depend on the processing

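Of the alternatives, background correction with neqc and the fixed LPS-responsive sets were chosen after the data were seen, as was the detection p on which the stricter filter rests. Of 173 recomputed comparison values 138 held. A count held if it stayed within 1.5 times the original, whatever the direction of its genes. A median of LPS-responsive genes held if it kept its sign and its side of the threshold. Of 8059 gene values 7490 kept direction and side of the threshold, 558 lost the call, 7 gained it and 4 reversed. Of 883 list values 811 kept both and 72 lost the call, 31 of these with an estimated correlation. With an added 2-fold threshold the counts were 276 and 375 for LPS in siCTL and siBcl3, 10 and 36 for siRNA at 8 h and 0 h, 7 for the interaction, and 17 and 311 for the average siRNA and LPS effects. Median scaling called 48 genes at 8 h (41.7% higher against 54.3%), 2 for the interaction (0% against 60%) and 484 for the average siRNA effect (64.3% against 49.5%). It also raised the share called higher at 0 h to 82.9% from 49.2%, and lowered it for LPS to 23.9% from 38.4% in siCTL, 13.3% from 38.2% in siBcl3 and 16.6% from 37.2% on average; there the median of all genes moved to -0.16 in siBcl3 and -0.12 on average. The authors' values called 55 interaction genes (76.4% higher), 27 of them among the 30, with 73.2% higher under cyclic loess and 71.4% with neqc. With only the arrays compared, 429 genes were called at 8 h and 304 at 0 h. The median siRNA effect at 8 h on LPS-induced genes was -0.0374 under median scaling, and that on LPS-repressed genes 0.0096 without background correction, 0.009 with cyclic loess and 0.0042 with the authors' values, all opposite in sign to the originals and none called. Reversed genes were Pcna (-0.042) and Insig1 (-0.047) for LPS in siBcl3 under median scaling, and Hspa8 for the average LPS effect with cyclic loess (0.052) and the authors' values (0.043). The cause was not tested for any of these. Leaving out 1 array, which assumes that the lone array varies like the other groups, gave 1874 to 2498 genes for LPS in siCTL, 2220 to 3187 in siBcl3, 3278 to 3619 on average, 22 to 357 for siRNA at 8 h, 214 to 578 at 0 h, 537 to 881 on average and 0 to 66 for the interaction (limma; 681 to 995 at an unadjusted p under 0.05). The low counts came without siBcl3 8 h replicate 1 (22), siCTL 8 h replicates 2 (32) and 1 (49), siBcl3 0 h replicates 1 (214) and 2 (369), and for the average without siBcl3 0 h replicate 1 (537), siBcl3 8 h replicate 1 (569) and siCTL 8 h replicates 2 (573) and 1 (611). The interaction called 66 genes without siCTL 0 h replicate 1, 25 without replicate 2, 22 without siBcl3 0 h replicate 2, 1 without siCTL 8 h replicate 2 or siBcl3 8 h replicate 2, and 0 without the other 3 arrays. Medians of LPS-induced genes ranged from 0.0068 to 0.035 and of LPS-repressed genes from -0.0586 to 0.0179 (0.0179 without siCTL 8 h replicate 1, 0.0087 without siBcl3 0 h replicate 2 and 0 without siCTL 8 h replicate 2); with the sets of all 8 arrays they ranged from 0.009 to 0.032 and from -0.028 to -0.011. Same-numbered arrays deviated together little (correlations -0.027 to 0.069), apart from the siBcl3 arrays at 0 h and 8 h (0.2). The labels do not state a pairing, so whether the numbers pair the samples stays unknown. With a replicate block the counts were 2525, 3113 and 3839 for LPS in siCTL, in siBcl3 and on average. For siRNA they were 281 at 8 h, 650 at 0 h and 1000 on average, and for the interaction 39. Signal over background limits dim genes: Bcl3 stood 11 to 99 units above the median chemosensory probe.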

Other observations

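The test of LPS-responsive genes at 0 h was chosen only after the result was seen. Members of further gene lists responded to LPS in control cells, though none of these lists was called with an estimated correlation. Of 17 apoptosis and survival genes 9 rose, led by Gadd45b (1.73), Casp4 (1.46), Bcl2a1d (1.37) and Mdm2 (0.82), and Mcl1 fell (-0.76), with 10 higher and 2 lower adjusted over the list alone (median 0.28, 0.18 to 0.28 with 1 array left out, camera adjusted p = 0.00221, and 0.136 with an estimated correlation). Among 10 immediate early genes Egr1 (1.91), Junb (1.88), Ier3 (1.35) and Atf3 (0.90) rose, while Fos (-0.81) and Jun (-0.39) fell, also adjusted over the list alone (median 0.24, adjusted p = 0.0426, and 0.17 with an estimated correlation). That list was not called without siCTL 8 h replicate 1 or 2, without a filter on dim probes or with a stricter one. The costimulation genes Cd40 (3.29) and Cd86 (0.94) rose and the class II accessory gene H2-DMa fell (-0.84), within an antigen presentation list of 7 higher and 2 lower genes, also adjusted over the list alone (median 0.26, 0.15 to 0.34 with 1 array left out, adjusted p = 0.00509, and 0.504 with an estimated correlation). Glycolysis genes Tpi1 (-0.94), Ldha (-0.61) and Pkm (-0.49) fell and the glucose transporter gene Slc2a1 rose (0.70), with a list median of 0.01, a mean of -0.14 and no call (adjusted p = 0.464). Of the macrophage markers Cd14, the LPS co-receptor gene, rose by 2.65, and Trem2 (-0.88), C1qb (-0.76) and C1qc (-0.74) fell (2 higher and 5 lower of 14, also adjusted over the list alone; list not called, adjusted p = 0.464). Of the lysosome and phagocytosis genes Fcgr2b rose (1.42) and Gas6 (-0.97), Fcgr3 (-0.93) and Atp6v0d1 (-0.75) fell (2 higher and 6 lower of 19, 3 and 7 adjusted over the list alone; list not called, adjusted p = 0.0946). S100a8 rose by 2.95 in the neutrophil list of 3 genes (adjusted p = 0.0426, and 0.173 with an estimated correlation), and the other 2 genes were not called. The list was lost without siCTL 0 h replicate 2 or siCTL 8 h replicate 2, with cyclic loess, with the authors' values and without a filter on dim probes. In siBcl3, 5 of 7 stromal markers rose with LPS, Sparc (0.54) and Cxcl12 (0.46) most (median 0.35, camera adjusted p = 0.00766, and 0.17 with an estimated correlation). The stromal list was not called for LPS in siCTL. The rise in siBcl3 is measured from the same siBcl3 0 h arrays on which these markers were low against siCTL. It is therefore not a separate observation.

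Regulators and receptors outside the largest changes also differed with Bcl3 siRNA. The transcription factor gene Klf4 changed by -1.17 at 0 h (adjusted p = 0.00011) and by -0.59 at 8 h (0.00523), and the cysteine protease gene Ctsk, an osteoclast marker, by -0.74 and -0.72. At 0 h the phagocytic receptor gene Axl (-0.92), the death receptor gene Fas (-0.72) and Mcl1 (-0.46) fell, and the fungal receptor gene Clec7a (0.68) and Fcgr2b (0.82) rose. Of the anti-inflammatory mediators Il1rn (-0.86), Socs3 (-0.84) and Nfil3 (-0.62) fell and Hmox1 rose at 0 h, with 5 lower and 1 higher (6 and 1 adjusted over the list alone) and no call for the list (median -0.04, adjusted p = 0.0608). At 8 h Dusp2 rose by 0.72. Heat shock genes had a median of -0.16 at 0 h (adjusted p = 0.0303, and 0.175 with an estimated correlation), with 0 of 9 called in limma or adjusted over the list alone and 1 at an unadjusted p under 0.05. That list was not called without siCTL 0 h replicate 2 or siBcl3 0 h replicate 2 (medians over the 8 fits -0.19 to -0.05), nor with median scaling, the stricter filter or fry. Cholesterol genes had a median of 0.09 (adjusted p = 0.0397, and 0.175 with an estimated correlation), with Fdps (0.38) higher, and were not called without siCTL 0 h replicate 1 or siBcl3 0 h replicate 2 (medians 0.06 to 0.13), nor with median scaling or the stricter filter. The NF-kB list was called at neither time (medians -0.03 at 0 h and 0.04 at 8 h, adjusted p = 0.574 and 0.91), nor were the cell cycle list (0.01 and 0.01, 0.6 and 0.895) and the Toll-like receptor list (-0.04 and 0.09, 0.752 and 0.146).

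LPS-responsive genes as a set were shifted in the siRNA comparison before LPS was given. Stromal markers fell in the same comparison (list median -0.41), and whether a changed cell mix contributed to the shift was not tested. The 227 LPS-induced genes had a median of -0.10 at 0 h, with 49 lower and 17 higher, and the 84 LPS-repressed genes one of 0.16, with 28 higher and 1 lower. Without siBcl3 0 h replicate 1 these counts were 24 lower and 5 higher, and 13 higher and 1 lower. Il1rn, Socs3, Vcam1 (-1.01) and Nupr1 (-1.10) were among the induced genes that fell, and Ccl3, Ccl4, Il1a and Tlr2 (0.35) among those that rose (chosen after their values were seen). In camera with an estimated correlation both sets passed (p = 0.00158 for induced and 0.00333 for repressed genes). With 1 array left out and the same sets, their medians were -0.123 to -0.098 and 0.156 to 0.183. The correlation was estimated between replicates that may not be separate cultures, on 4 residual degrees of freedom. The test therefore cannot exclude a chance shift between cultures. Under median scaling, with all genes at 0.06, neither set passed in camera with an estimated correlation (0.394 and 0.103). The induced set, there of 167 genes, had a median of -0.008 (12 higher and 14 lower), so its shift may depend on normalization. Its estimated correlation was 0.284 under median scaling, against 0.002 in the main setting. The repressed set, there of 188 genes, had one of 0.348 (64 higher and 1 lower): its change was not smaller, but the estimated correlation was 0.344 against 0.017.

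The effects averaged over 4 arrays against 4 were set against other splits of the 8 arrays, in a model with the other factor as a term. For Bcl3 siRNA 1 of 34 splits, the real one, called as many as its 712 genes, and the highest other split called 0 in limma (at most 899 at an unadjusted p under 0.05, against 1900). For LPS 1 of 34 splits, the real one, called as many as its 3686 genes, and the highest other called 0 in limma (at most 736, against 4272). Every other split left the real effect in its residual spread, so low counts there were favoured in advance. The splits therefore do not exclude chance for either count.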
